A study of Homo sapiens with 28 samples.

How the data were processed

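Gene expression was measured by sequencing poly(A)-selected RNA from U937 cells, a human monocytic line. The libraries were stranded and read as pairs of 76 bases, per the labels' protocols. Per the same protocols, cells were treated with the phorbol ester PMA at 10 ng/mL for 48 h, kept in fresh medium overnight and then given LPS at 10 ng/mL or water for 6 h, and the WT clones went through the same steps as the edited ones without the editing plasmids. Libraries were grouped by genotype and treatment as the labels give them, into 8 groups: KO and its WT (4 clones each) and KI, homozygous for C103A, and its WT (3 clones each), each under vehicle and LPS. The unsorted WT sample is labelled as WT and was kept in the WT group of the KO set; it is counted as 1 of the 14 clones, though whether it is a clone or a pool is not given in the sources used here.

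The deposited table holds raw counts per gene for 60279 Ensembl gene identifiers in 28 libraries, which the authors made with bcl2fastq (no version given), HISAT2 2.0.2 and featureCounts 1.4.4 on genome build hg38, per the submitters' processing notes. The annotation and the strand setting used for counting are not stated, so counts of genes that overlap or face each other, or that share reads with a near-identical copy, are uncertain. Names, types and coordinates were taken from GENCODE release 29 (GRCh38), which matched 56590 of the identifiers and left 3689 unmatched; unmatched genes were tested and not named. Column totals, taken as the depth, ran from 7539406 to 21074772 counts. A gene with no count over a group was given a floor of 3 reads over that group, and low counts were given 95% counting intervals (exact binomial, conditional on the sum). Levels of Y-linked genes and XIST are not reported here.

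All computations used R 4.3.3 and Python 3.11.15, with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package (1.17.8) and matplotlib 3.10.9. Genes were kept by filterByExpr with the 8 groups (minimum count 10, minimum total 15), which left 13399. One edgeR quasi-likelihood model with 8 group means and TMM scaling was fitted to all 28 libraries, and 12 contrasts were tested: KO against WT and KI against WT under each treatment, LPS against vehicle in each genotype set, the difference of LPS responses for KO and KI, and KO effect minus KI effect under each treatment. All adjusted p-values of genes are from that test with Benjamini-Hochberg adjustment over the tested genes unless another tool is named; a gene was called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes. The fold changes of genes with at most 3 reads in a group are ratios of reads scaled in the same way.

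In the KO and KI contrasts the clone is the unit of replication, and whether the clones of a genotype are independent was not tested. Each clone gave a vehicle and an LPS library, a pairing stated by the clone names. Across genes, the deviations of those libraries from their group means correlated at r = 0.403 to 0.863, and each of the 14 clones correlated best with itself. The fit with the clone as a block is therefore given beside LPS responses and their differences.

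The 20 gene lists, with 554 genes of which 498 were tested, were fixed before the data were examined, as were the groups, the contrasts and the alternatives tried, save those named below as added. They cover NF-kB feedback and target genes, cytokines, chemokines, type I interferon-stimulated genes, interferon-gamma and antigen presentation genes, the LPS and Toll-like receptor pathway, A20 partners and ubiquitin machinery, immediate-early and MAPK feedback genes, inflammasome and lytic cell death genes, apoptosis regulators, macrophage and monocyte markers, immature myeloid markers, proliferation genes, proteases with matrix and adhesion genes, glycolysis and hypoxia genes, cholesterol and lipid genes, unfolded protein and integrated stress response genes, oxidative stress genes with metallothioneins, markers of other cell types, and mitochondrially encoded genes as a measure of RNA quality. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a contrast, and again with an estimated correlation and with fry. Counts adjusted over the list alone apply Benjamini-Hochberg to the members only.

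Genes named in the text follow a rule fixed at the same time. It takes TNFAIP3 in every contrast and, in genotype contrasts, the up to 8 largest fold changes each way among called genes with a mean of at least 2 CPM in the higher group and no overlap between the groups. It takes 6 higher and 4 lower in LPS responses and 4 each way in differences of effects, with up to 2 called members per list added everywhere. Genes without a symbol, pseudogenes and non-coding genes were left out, and the text uses fewer names than the rule allows, preferring calls that held whichever clone was left out.

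Induced and repressed genes for the response per clone were taken from the LPS calls of at least 2-fold in the WT of the other set, and the clone means were compared with exact permutation tests. List scores are means of log2 CPM with a prior count of 2. Chromosome medians used genes with a mean log2 CPM of at least 3, with bins of 10 Mb and a boundary at 60 Mb on chromosome X chosen after the data were seen.

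The edgeR contrasts, the list tests for KO against WT after LPS and the chromosome X shift were tested on simulated counts (seed 11). These counts used the means and spreads fitted to the real genes, with 200 genes changed for the contrasts. The permutation tests, the overlap of KO and KI calls and the clone correlations were not tested in this way. In KO against WT after LPS 46.3% of 2-fold, 73.1% of 4-fold and 84.8% of 8-fold changes were recovered, with 4 unchanged genes called. In KI against WT after LPS the shares were 29.9%, 70.1% and 83.3%, with 15 unchanged genes called. Apart from a blocked run, simulated libraries were drawn independently around a mean common to all groups, save for the changed genes. They had no clone levels or pairing, so the shares may differ for the real clones.

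The alternatives chosen at the outset were RLE size factors, no filter, DESeq2, limma voom with the clone as a random effect, fits of the 16 libraries of the KO set or the 12 of the KI set alone, each clone left out in turn, and the replicate blocks. Alternatives added after the data were seen were library size alone, the level of chromosome 6 genes between 40 and 60 Mb, of the proliferation list or of the interferon list as a covariate, the fit without KO4, KO5, WT3 and WT6, and counts without chromosome X. Other splits of the samples were enumerated, or 100 drawn where there were more (seed 1), and for KO effect minus KI effect all 70 assignments of the KO-set clones were also counted with the KI clones kept together. No library was left out.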

Results

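Messenger RNA was measured in 28 libraries of U937, an established human monocytic cell line, made macrophage-like with the phorbol ester PMA and then given LPS or its water vehicle for 6 h. LPS is the bacterial wall component that activates Toll-like receptor 4. The libraries came from 14 clones, each with a vehicle and an LPS library, counting the unsorted WT as 1 of them; whether that sample is a clone or a pool is not given in the sources used here. There were 4 clones with the ubiquitin-editing gene A20 (TNFAIP3) knocked out (KO) and 4 wild-type (WT) clones of the same set, KO1, KO2, KO4, KO5, WT1, WT2, WT3 and an unsorted WT. A further set held 3 clones homozygous for the A20 substitution C103A, described in the labels as inactivating its deubiquitinase domain (KI1, KI2, KI3), with WT4, WT5 and WT6. The study asked what A20 and this domain do to gene expression in human macrophage-like cells. Total counts ran from 7539406 to 21074772 per library. They spanned 14665416 to 19849748 in KO after LPS, 14311892 to 18814114 in its WT, 14599003 to 20810754 in KI after LPS and 12149413 to 21074772 in its WT. Under vehicle they were 10986456 to 17926167 in KO, 7539406 to 13641831 in its WT, 11009192 to 13349804 in KI and 9048711 to 18746742 in its WT. Mitochondrially encoded genes took between 0.969% and 1.74% of the counts. Clones were the replicates. The p-values of the main model set a difference against the spread between libraries of a group, each from another clone. That model takes all 28 libraries as independent, though the libraries of a clone correlated at 0.703 in limma voom. Whether the clones are independent of each other was not tested. After filtering, 13399 genes were tested.

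TNFAIP3 encodes A20 itself, a brake on NF-kB signalling that NF-kB also induces. Its transcript (ENSG00000118503, GRCh38 chromosome 6, 137867188 to 137883312) was present in every library, including all of those labelled KO. The labels do not state what the edit does to the transcript, so these counts do not check the KO labels. Under vehicle TNFAIP3 stood at 39.2 ± 4.18 counts-per-million (CPM; mean ± SD, n = 4) in KO and 41.5 ± 20.8 CPM in WT (n = 4). After LPS it reached 1681 ± 411 CPM in KO, with clones from 1077 to 1978 CPM, against 391 ± 58.6 CPM in WT, with clones from 327 to 457 CPM. That difference passed the test (log2 fold change 2.10, SE 0.30, adjusted p = 3e-04), and the vehicle difference did not (log2 fold change -0.08, adjusted p = 0.989). In the KI clones the mutant transcript stood at 106 ± 27.3 CPM under vehicle (n = 3) against 50.3 ± 10.96 CPM in WT (n = 3). The KI clones ran from 80.0 to 134 CPM and their WT from 37.9 to 58.6 CPM, but the difference missed the threshold (log2 fold change 1.08, adjusted p = 0.113). After LPS the KI level of 510 ± 114 CPM lay within the spread of the WT level of 430 ± 142 CPM (log2 fold change 0.25, adjusted p = 0.782). Leaving out any clone kept the KO call after LPS.

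**Figure D1:**
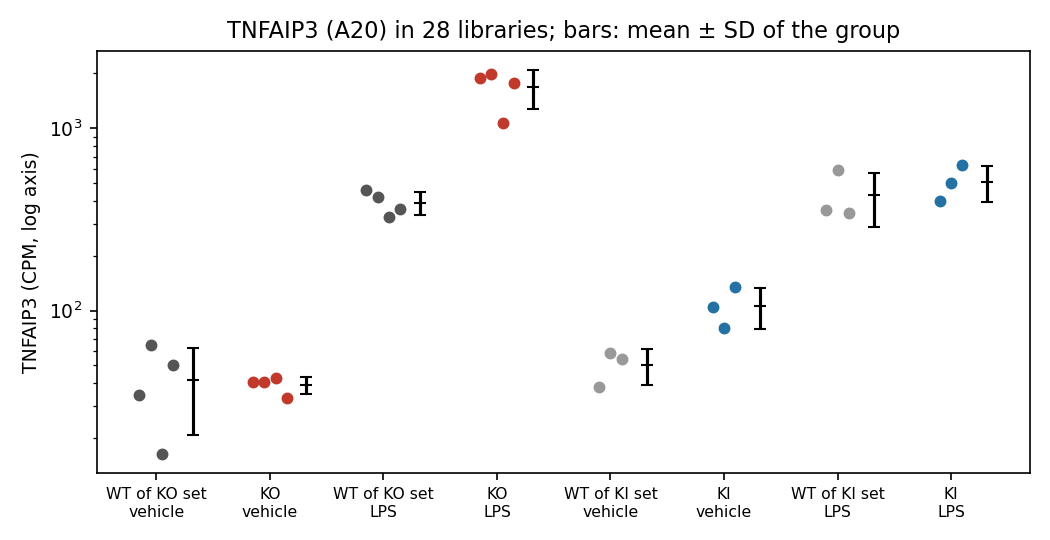
TNFAIP3 in each of the 28 libraries (points, CPM on a log axis) by genotype set and treatment, with the group mean and SD as bars. The 4 KO clones after LPS sit between 1077 and 1978 CPM, above the 4 WT clones at 327 to 457 CPM.

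LPS switched on an inflammatory programme in all 4 genotype sets. The prostaglandin synthase PTGS2, the A20-binding NF-kB inhibitor TNIP3, the neutrophil-attracting chemokine CXCL2, the protease inhibitor SERPINB2, the vasoactive peptide ADM, the fatty acid activating enzyme ACSL1 and TNFAIP3 itself rose in each set. NF-kB feedback and target genes responded almost as a whole list. Type I interferon-stimulated genes were rarely called without the pairing of libraries by clone, and more often with it. The number of genes called was 1539 in the WT of the KO set (974 higher, 565 lower), 4025 in KO (1915 higher, 2110 lower), 644 in the WT of the KI set (480 higher, 164 lower) and 860 in KI (653 higher, 207 lower). With the clone as a block, which pairs the vehicle and LPS library of a clone, they were 5513, 7765, 3845 and 4369. Without the block the count in the WT of the KO set was 918 without WT2, 864 without WT3 and 757 without the unsorted WT, that in the WT of the KI set 196 without WT4, 323 without WT5 and 394 without WT6, and that in KI 383 without KI1, 203 without KI2 and 300 without KI3. Of the calls without the block, 367 genes were higher and 88 lower in all 4 sets. The share of higher calls rests on the scaling: with library size alone it was 16% against 63.3% in the WT of the KO set, 10.4% against 47.6% in KO, 31.6% against 74.5% in the WT of the KI set and 35.9% against 75.9% in KI. That scaling moved the median gene by -0.36, -0.67, -0.31 and -0.28 in log2.

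PTGS2 (ENSG00000073756, chromosome 1, 186671791 to 186680427) went from 2.17 ± 1.35 to 1146 ± 752 CPM in the WT of the KO set (log2 fold change 8.99, adjusted p = 5.23e-10) and from 8.64 ± 3.90 to 9475 ± 2009 CPM in KO (10.10, adjusted p = 3.66e-11). Its log2 fold change was 8.16 in the WT of the KI set and 8.64 in KI. TNFAIP3 rose by a log2 fold change of 3.24 in the WT of the KO set (adjusted p = 3.22e-07), 5.42 in KO (1.71e-10), 3.10 in the WT of the KI set (9.32e-06) and 2.27 in KI (0.000211). CXCL2 rose by 6.71, 7.93, 6.29 and 7.65 in the same order, and ACSL1 by 3.41, 4.06, 3.67 and 3.05. These calls, and those of TNIP3, SERPINB2 and ADM, held whichever clone was left out, though limma voom called TNIP3 in KO only; without WT6 the log2 fold change of TNIP3 in the WT of the KI set moved from 7.98 to 11.98. IL2RA, the high-affinity interleukin-2 receptor chain, went from no reads under vehicle to a level at least 133-fold higher in the WT of the KO set, at least 556-fold higher in the WT of the KI set and at least 771-fold higher in KI, against a floor of 3 reads over the group. The granulocyte growth factor CSF3 rose 478-fold in the WT of the KO set (95% counting interval 132 to 3950) and 5450-fold in KO (1860 to 26400). Such intervals and floors cover counting error only, and limma voom called neither IL2RA in the WT of the KO set or of the KI set nor CSF3 in the WT of the KO set. Among repressed genes, the microtubule-associated MTUS1 fell by 2.90 in log2 in the WT of the KO set and by 3.38 in KI. In KO the stem cell transcription factors HOXA9 and MEIS1 fell by 2.56 and 2.66, and the myeloid factor CEBPA fell by 2.17.

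In the list of NF-kB feedback and target genes, LPS raised 29 of 32 members in the WT of the KO set, 32 in KO, 28 in the WT of the KI set and 28 in KI. Their median log2 fold changes were 2.79, 3.82, 2.75 and 2.94, and the list test held in each set with an estimated correlation (highest adjusted p = 6.29e-06). Of 23 cytokines, 18, 20, 12 and 15 rose, and this list also held in each set (highest adjusted p = 0.0156 with an estimated correlation; 21, 20, 20 and 21 rose with the clone as a block). Of 23 chemokines 9, 12, 10 and 9 rose, and 20, 21, 19 and 18 with the block; their test held in 3 sets and was lost in KO (adjusted p = 0.177 with an estimated correlation, 0.062 with the block). Of 29 interferon-gamma and antigen presentation genes 5, 8, 2 and 2 rose, and 20, 18, 16 and 13 with the block. Apoptosis regulators were higher for 7, 10, 3 and 4 of 23 members, and for 13, 14, 13 and 11 with the block, a test likewise lost in KO (adjusted p = 0.052 with an estimated correlation). Of 37 type I interferon-stimulated genes 0, 1, 0 and 0 were called; with the clone as a block 15, 8, 14 and 6 were higher and 0, 3, 0 and 1 lower. The 13 mitochondrially encoded genes, a measure of RNA quality, rose with the block for 5, 12, 12 and 0 members (0, 2, 0 and 0 without it); camera passed in KO and in the WT of the KI set (adjusted p = 0.0222 and 0.0227, lost at 0.618 and 0.632 with an estimated correlation).

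After LPS, KO clones carried much more cytokine and NF-kB target transcript than their WT. TNF, the main inflammatory cytokine of macrophages, the anti-inflammatory cytokine IL10, the chemokine CXCL2 and PTGS2 were all higher in KO. So were IRF1, an interferon-regulatory factor, NLRP3, the inflammasome sensor, and ADM. HMOX1, the haem-degrading enzyme of the oxidative stress response, SPRY2, a brake on MAPK signalling, the deubiquitinase USP2 and FADD, the adaptor of death receptors, were lower. All 32 tested NF-kB feedback and target genes had a positive fold change. Of the tested genes 873 were called, 444 higher and 429 lower in KO (50.9% higher), and 394 of them changed at least 2-fold (212 higher, 182 lower). With library size alone, which moved the median gene by -0.42 in log2, 6.93% of the calls were higher, so the balance between the directions depends on the scaling. The count was 570 without KO4, 413 without KO5, 298 without WT1 and 433 without the unsorted WT, and lay within 1.5 times the full count without any other clone.

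TNF (ENSG00000232810, chromosome 6, 31575567 to 31578336) stood at 1151 ± 865 CPM in KO against 45.4 ± 31.0 CPM in WT (log2 fold change 4.66, SE 0.69, adjusted p = 0.000341). IL10 stood at 1409 ± 700 against 78.1 ± 64.1 CPM (4.17, SE 0.79, adjusted p = 0.00279), PTGS2 at 9475 ± 2009 against 1146 ± 752 CPM (3.05, SE 0.44, adjusted p = 3e-04) and CXCL2 at 1577 ± 380 against 175 ± 81.7 CPM (3.17, SE 0.54, adjusted p = 0.00101). The epithelial-acting cytokine IL20 gave 100 reads in KO and 1 in WT, a 117-fold ratio (95% counting interval 20.6 to 4680). IRF1 reached 72.5 ± 7.87 against 24.7 ± 7.63 CPM (adjusted p = 0.00102), NLRP3 272 ± 105 against 80.7 ± 29.5 CPM (adjusted p = 0.00196) and ADM 130 ± 38.8 against 19.1 ± 10.7 CPM (adjusted p = 0.00279). USP2 fell by 2.13 (5.35 ± 0.935 against 23.5 ± 14.1 CPM, adjusted p = 0.000376), SPRY2 by 1.75 (35.6 ± 8.87 against 120 ± 52.3 CPM, adjusted p = 0.0013) and FADD by 0.68 (16.3 ± 3.68 against 26.1 ± 1.30 CPM, adjusted p = 0.00542). HMOX1 fell by 2.00 (adjusted p = 0.00756), and by 1.28 without WT3, whose level was the highest in its group. The calls named in this paragraph up to here held whichever clone was left out, but IL10, NLRP3, ADM and HMOX1 lost theirs without the 4 clones low in proliferation genes (KO4, KO5, WT3 and WT6), and HMOX1 also with limma voom. The largest fold changes included others that did not: IL1A, CSF2 and IL6 (log2 fold changes 4.24, 4.12 and 3.91) each lost the call without any of the clones except WT2, with adjusted p up to 0.135, 0.115 and 0.176. FCAMR, an Fc receptor (3.65), lost it without KO4, WT1 or the unsorted WT (adjusted p up to 0.0965), and stood at 2.13 without KO4. The integrin ITGB3 (3.59) lost it without WT1 or the unsorted WT (up to 0.0611). The protease BACE2 (-5.25) lost it without KO2, KO4, KO5 or WT1 (up to 0.083) and stood at -8.996 without KO1, and the urea cycle enzyme CPS1 (-3.84) without KO2, KO4, KO5, WT1 or the unsorted WT (up to 0.112).

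By list, 17 of 32 NF-kB feedback and target genes were higher in KO after LPS and none lower (25 higher adjusted over the list alone), with a median log2 fold change of 1.28; 10 were called without WT1 and 10 without the unsorted WT. Of 23 cytokines 10 were higher and none lower (16 adjusted over the list alone), median 2.60. The count was 4 without KO5, 4 without WT1, 6 without WT3 and 5 without the unsorted WT. It was 6 with the KO set fitted alone and 5 without the 4 clones low in proliferation genes. In these fits, which hold fewer samples, the list median ran from 2.165 without KO5 to 2.61 with the set fitted alone. The lowest cytokine median of any fit was 1.949, without KO1, where 7 were called. NF-kB targets and cytokines were the only lists whose camera test held with an estimated correlation (adjusted p = 0.00191 and 0.01). Of 23 chemokines CXCL2 and CCL5 were higher (5 adjusted over the list alone; median 1.04, adjusted p = 0.336 with an estimated correlation); CCL5 lost its call without KO5 or WT1 (adjusted p up to 0.0766). Glycolysis and hypoxia genes had 4 of 25 higher (8 adjusted over the list alone; median 0.50), among them ADM, with adjusted p = 0.31 with an estimated correlation. Proteases, matrix and adhesion genes had 3 of 29 higher (4 adjusted over the list alone; median 1.17, adjusted p = 0.31 with an estimated correlation). The unfolded protein and integrated stress response list had 2 of 26 higher, CHAC1 and XBP1 (3 adjusted over the list alone; median 0.25, adjusted p = 0.336 with an estimated correlation), both lost without the 4 clones low in proliferation genes. Immediate-early and MAPK feedback genes went both ways, with 4 of 31 higher, DUSP2 among them, and SPRY2 lower (5 higher and 2 lower adjusted over the list alone; median 0.27, adjusted p = 0.475 with an estimated correlation; fry test for a change in either direction, adjusted p = 7.88e-09). The list of inflammasome and lytic cell death genes had 2 of 19 higher, NLRP3 and CASP4 (3 adjusted over the list alone; median 0.12, adjusted p = 0.475 with an estimated correlation); CASP4 kept its call only without KO1 or WT2 (adjusted p up to 0.203). The interferon-gamma and antigen presentation list had only IRF1 of 29 higher, also adjusted over the list alone (median 0.37, adjusted p = 0.475 with an estimated correlation).

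The A20 partners had BIRC2 higher and FADD lower of 26 (2 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.425 with an estimated correlation); the BIRC2 call was lost without KO4, KO5, WT1, WT3 or the unsorted WT (adjusted p up to 0.144). The Toll-like receptor pathway had 2 of 25 higher, TICAM1 and TRAF6 (2 adjusted over the list alone; median 0.20, camera adjusted p = 0.097). TICAM1 lost its call without WT1 or the unsorted WT (up to 0.0645), and TRAF6 without any clone except KO5 or WT3 (up to 0.161). Apoptosis regulators had 2 of 23 higher and 1 lower (3 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.118). Oxidative stress and metallothionein genes had 1 of 25 higher and 2 lower, in both ways of adjusting (median 0.30, camera adjusted p = 0.265). Among 27 cholesterol and lipid genes only INSIG1, a feedback regulator of sterol synthesis, was higher (log2 fold change 1.68, adjusted p = 0.00862), also adjusted over the list alone, while the list median was -0.32 (camera adjusted p = 0.294). Of 34 macrophage and monocyte markers only CEBPA changed, by -1.10 (adjusted p = 0.0303), also adjusted over the list alone; it lost the call without KO4, KO5, WT1 or the unsorted WT (up to 0.145), and the list median was 0.47 (adjusted p = 0.475 with an estimated correlation). No member passed among 37 type I interferon-stimulated genes (median 0.20, camera adjusted p = 0.118), 15 immature myeloid markers (-0.92, 0.0932), 30 proliferation genes (-0.98, 0.00833, lost at 0.651 with an estimated correlation), 13 mitochondrially encoded genes (0.39, 0.00848, lost at 0.475) or 6 markers of other cell types (-0.26, 0.882, a test pointing up while the mean was -0.07), nor adjusted over each list alone. Proliferation genes were low in 4 clones of both kinds. Their mean log2 CPM was averaged over the vehicle and LPS library of each clone. It was 3.25 in KO4, 3.32 in KO5, 3.28 in WT3 and 2.29 in WT6, against 4.82 to 6.07 elsewhere.

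**Figure D2:**
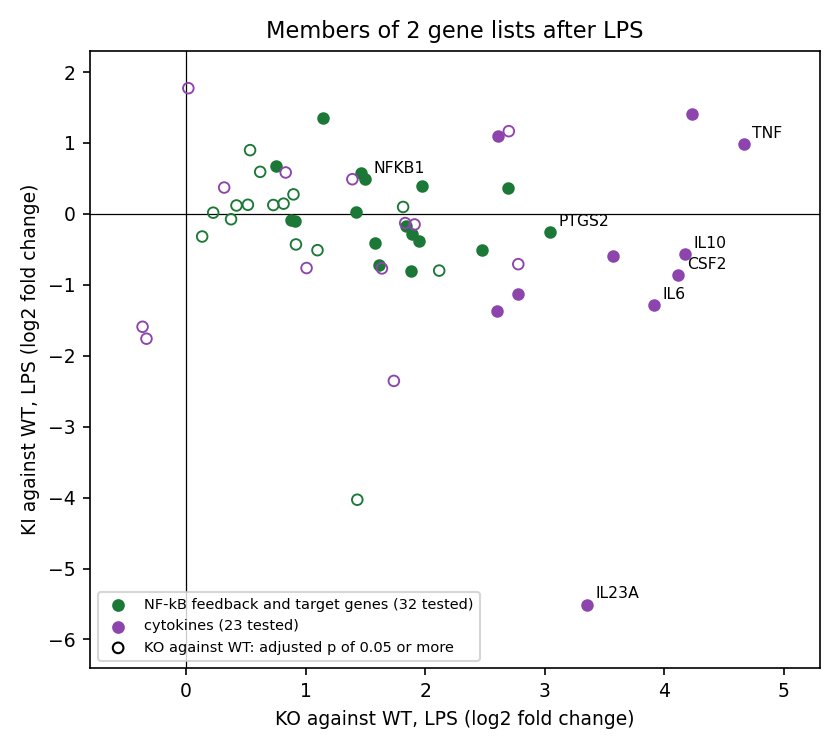
Log2 fold change after LPS in KO against WT (horizontal axis) and in KI against WT (vertical axis) for the 32 NF-kB feedback and target genes (green) and 23 cytokines (purple); filled points passed in KO. All 32 NF-kB members lie to the right of 0, and 16 of them above 0 on the vertical axis.

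Without LPS few or no genes were called between KO and WT, in a test that recovered 41.8% of 2-fold changes on simulated data. TNF stood at 3.00 ± 1.88 CPM in KO and 3.70 ± 3.06 CPM in WT, and NFKB1, the precursor of the NF-kB subunit p50, at 62.9 ± 12.5 and 64.0 ± 9.13 CPM. As a group, NF-kB targets leaned upward all the same. No gene passed by edgeR (683 at an unadjusted p under 0.05; lowest adjusted p = 0.148), DESeq2 called 9 and limma voom 1, and edgeR called 3 without WT2, 1 without KO4 and 1 without the unsorted WT. Of 32 NF-kB feedback and target genes 29 had a positive fold change (median 0.50), and 2 were higher adjusted over the list alone. The camera tests of this list, cytokines, chemokines, both interferon lists, inflammasome genes, A20 partners, macrophage markers, proteases and both metabolic lists of glycolysis and oxidative stress passed upward and proliferation downward (all 30 members negative, median -0.84). None of them held with an estimated correlation (NF-kB adjusted p = 0.173, cytokines, chemokines, proteases and glycolysis 0.276, proliferation 0.472).

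The LPS response itself differed between the KO clones and their WT, in many more genes with the libraries paired by clone than without. TNF, TNFSF9, the ligand of the co-stimulatory receptor 4-1BB, NFKB1 and TNFAIP3 were near the WT level under vehicle and rose further in KO. FADD fell under LPS in KO. NFKB1 went from 62.9 ± 12.5 to 791 ± 67.0 CPM in KO and from 64.0 ± 9.13 to 280 ± 36.0 CPM in WT. The difference of the responses called 21 genes, 15 of them larger in KO and 6 smaller; RLE size factors gave 85.7% higher against 71.4%, and library size alone 17.5%, with the median gene moved by -0.32. With the clone as a block 1105 genes were called, 48.1% of them higher. Without the block the count was 14 without KO1, 1 without KO2, 2 without KO4, 1 without KO5, 1 without WT1, 9 without WT2, 5 without WT3 and 1 without the unsorted WT.

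NFKB1 was the only named gene whose difference of responses held whichever clone was left out (log2 difference 1.52, SE 0.20, adjusted p = 0.00168, at most 0.0243; blocked 1.54, adjusted p = 0.000259). TNF responded more by 4.94 (SE 0.92, adjusted p = 0.0379), TNFSF9 by 2.72 (adjusted p = 0.0424), TNFAIP3 by 2.18 (adjusted p = 0.0379) and the transcriptional coactivator CITED4 by 1.82 (adjusted p = 0.0379). Smaller responses were -1.94 for KBTBD7 (adjusted p = 0.0379), -1.53 for PIK3IP1 (0.0496), -1.33 for the zinc exporter SLC30A1 (0.0424), -1.29 for RAP2B (0.0496) and -0.95 for FADD (0.0496). TNF, TNFSF9, KBTBD7, PIK3IP1 and RAP2B lost the call without any of the 8 clones (adjusted p up to 0.173, 0.212, 0.218, 0.231 and 0.261), TNFAIP3 without any but WT3 (0.218) and FADD without any but KO4 (0.26). CITED4 and SLC30A1 lost it without KO2, KO4, KO5, WT1, WT3 or the unsorted WT (0.173 and 0.218). With the block they were 4.74 for TNF (adjusted p = 0.000152), 2.87 for TNFSF9 (0.000353), 2.02 for TNFAIP3 (0.00259), 1.81 for CITED4 (0.00198) and -0.95 for FADD (0.000707). Of the NF-kB feedback and target genes 1 of 32 was called (6 adjusted over the list alone, 11 with the block; median 0.70), and of cytokines 2 of 23 (3 adjusted over the list alone, 4 with the block; median 1.06). Their tests were lost with an estimated correlation (adjusted p = 0.0797 and 0.126), and with the block as well (0.0644 and 0.062), while the blocked fry test gave adjusted p = 0.00314 for each. The 13 mitochondrially encoded genes moved the same way: 0 were called without the block and 10 were higher with it (blocked camera adjusted p = 7.08e-08, lost at 0.231 with an estimated correlation; blocked fry 0.00314).

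Genes that LPS induced in the WT of the other set gave a measure per clone that used neither KO nor its own WT to choose them. Over 351 induced genes the mean log2 response was 3.13 ± 0.16 in KO and 2.3 ± 0.21 in WT (n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible, adjusted 0.0572 over 4 such tests). It was larger in KO for 305 of these genes. Over 91 repressed genes the mean response was -2.18 ± 0.30 in KO and -1.51 ± 0.22 in WT (exact permutation p = 0.0286, two-sided, the smallest possible, adjusted 0.0572). In KI the 483 induced genes gave 2.18 ± 0.23 against 2.13 ± 0.23 (n = 3 each; exact permutation p = 0.8, two-sided, smallest possible 0.1).

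**Figure D3:**
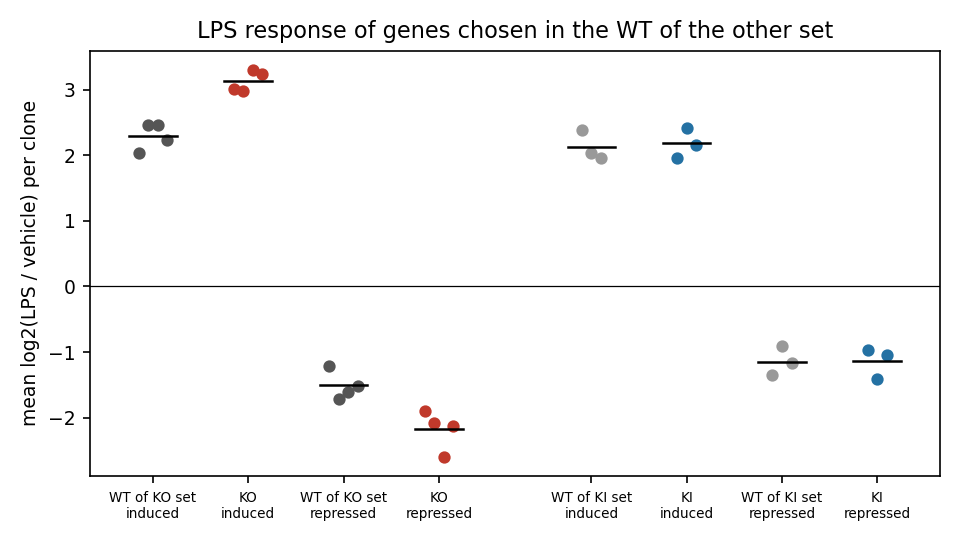
Mean log2 ratio of LPS to vehicle in each clone (points; lines are group means) over genes induced or repressed in the WT of the other set. KO clones average 3.13 against 2.3 in their WT for induced genes, and KI clones 2.18 against 2.13.

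The C103A clones differed from their WT under vehicle, where edgeR called no gene in KO. The profiles of the 3 KI clones across genes correlated at 0.74 or more, against 0.55 at most between clones outside KI. If the KI clones share a recent parent cell, the KI p-values and the fits without 1 clone do not rest on independent clones. The immune receptors FCGR2B, an inhibitory Fc receptor, and TREM1, an amplifier of myeloid activation, were lower in KI, as were CYBB, the catalytic subunit of the phagocyte oxidase, and the glycolytic enzyme PGK1. Several genes were all but absent from one group of clones. OXR1 and TM6SF1 were found in KI and hardly in WT4, WT5 and WT6, ABHD8 and ZNF585A in those WT clones and hardly in KI. After LPS OXR1 was also called lower in KO than in the WT of the KO set (log2 fold change -4.455). It was therefore not absent from all WT clones. In KI under vehicle no NF-kB feedback or target gene was called. Of the tested genes 256 were called, 52 higher and 204 lower (20.3% higher; 36% with library size alone), and 179 changed at least 2-fold (31 higher, 148 lower). The count was 116 without KI1, 65 without KI2, 67 without KI3, 154 without WT4 and 424 without WT5.

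ABHD8 (ENSG00000127220, chromosome 19, 17292131 to 17310236) was 939-fold lower in KI (95% counting interval 168 to 37100), and ZNF585A (ENSG00000196967, chromosome 19, 37106734 to 37172741) and the B-cell adaptor BLNK were at least 57.1-fold and at least 32.7-fold lower. TM6SF1, GJA5, GAREM1 and ADAM28 were at least 148-fold, 84.2-fold, 61.3-fold and 36-fold higher in KI. OXR1 was 256-fold higher (70.5 to 2120) and the mannosidase MAN1A1 117-fold (39.7 to 569). PGK1 stood at 651 ± 48.9 against 1669 ± 461 CPM (log2 fold change -1.36, adjusted p = 0.00302). These calls held whichever clone was left out. GPC4 (ENSG00000076716, chromosome X, 133300103 to 133415490) gave 6710 reads in KI and 1 in WT, a 6780-fold ratio (1220 to 268000), with the call lost without WT4 (adjusted p = 0.0569), with the KI set fitted alone, with limma voom, with the chromosome 6 segment or the interferon list as a covariate and without the 4 clones low in proliferation genes. FCGR2B stood at 2.97 ± 0.636 against 55.6 ± 51.7 CPM (log2 fold change -4.22, adjusted p = 0.00386, and 0.0505 without KI2). TREM1 (14.2 ± 5.39 against 105 ± 40.9 CPM, log2 fold change -2.89, adjusted p = 0.0186) lost the call without KI1, KI2, KI3 or WT4 (up to 0.148). CYBB (29.2 ± 6.89 against 1060 ± 944 CPM, log2 fold change -5.18, adjusted p = 0.0058) lost it without KI2 or KI3 (up to 0.0777) and with the KI set fitted alone.

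In KI under vehicle 0 of 32 NF-kB feedback and target genes were called (0 adjusted over the list alone; median -0.08 and a test pointing up, camera adjusted p = 0.868). Macrophage and monocyte markers had 3 of 34 lower (6 lower and 1 higher adjusted over the list alone; median -0.91), and chemokines 1 of 23 lower (8 adjusted over the list alone; median -1.29). None of 37 type I interferon-stimulated genes was called, over all genes or adjusted over the list alone, though 36 had a negative fold change (median -1.81). Stress response genes had 4 of 26 lower adjusted over the list alone (median -0.58), and mitochondrially encoded genes 3 of 13 higher adjusted over the list alone (median 0.53). Camera passed for these lists, interferon-stimulated genes at 2.87e-07, but each had adjusted p = 0.857 with an estimated correlation.

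After LPS FCGR2B, CYBB and PGK1 stayed low in the KI clones, while no NF-kB feedback or target gene was called. ABHD8 and ZNF585A were again nearly absent, and GPC4, OXR1, MAN1A1 and TM6SF1 again high. TNF, IL10 and PTGS2, higher in KO, did not pass in KI. On simulated data that test recovered 29.9% of 2-fold, 70.1% of 4-fold and 83.3% of 8-fold changes. IL23A, a subunit of interleukin-23, was the only cytokine called, and it was lower. Of the tested genes 370 were called, 113 higher and 257 lower (30.5% higher; 53.8% with library size alone), and 233 changed at least 2-fold. The count was 140 without KI1, 69 without KI2 and 110 without KI3.

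OXR1 was 251-fold higher (69.1 to 2070), TM6SF1 284-fold (50.6 to 11200), GPC4 at least 2260-fold (a call lost with the KI set fitted alone, with limma voom and with the interferon list as a covariate) and MAN1A1 at least 75.9-fold; ABHD8 was 814-fold lower (146 to 32200) and ZNF585A at least 54.1-fold lower. FCGR2B stood at 3.52 ± 0.879 against 67.4 ± 65.2 CPM (log2 fold change -4.26, adjusted p = 0.00311). Each of these calls held whichever clone was left out. PGK1 (820 ± 76.1 against 1819 ± 450 CPM, log2 fold change -1.15, adjusted p = 0.01) lost its call without KI1 or KI3 (up to 0.0649), and CYBB (-4.68, adjusted p = 0.00961) without any KI clone (up to 0.0815) and with the KI set fitted alone. IL23A (3.23 ± 0.847 against 147 ± 226 CPM, log2 fold change -5.51, adjusted p = 0.0115) lost it without any KI clone or WT6 (up to 0.127), with the KI set fitted alone, with limma voom and without the 4 clones low in proliferation genes, and stood at -2.37 without WT6. None of the 32 NF-kB members was called, 16 of them having a positive fold change (0 adjusted over the list alone; median -0.03 and a test pointing up, camera adjusted p = 0.719). Of 37 interferon-stimulated genes 0 were called and 5 were lower adjusted over the list alone, with all 37 negative (median -2.00; camera adjusted p = 2.75e-10, and 0.931 with an estimated correlation). Their list mean was 3.14 ± 0.37 log2 CPM in KI and 5.07 ± 0.22 in WT (n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). Macrophage markers had 3 of 34 lower (10 lower and 1 higher adjusted over the list alone; median -0.95, adjusted p = 0.931 with an estimated correlation).

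The lower genes of the KI clones were gathered on chromosome X, where PGK1 and IRAK1 lie beyond 60 Mb; CYBB, also lower, lies before it. The call of IRAK1 after LPS was lost without any KI clone, WT4 or WT5 (up to 0.193) and with library size alone. Of the 204 lower genes under vehicle 73 lay there (35.8%), and of the 257 after LPS 78 (30.4%), while 3.18% of the tested genes did (Fisher's exact test across genes, which are not independent replicates, two-sided p = 8.74e-58 and 1.63e-55). From 60 Mb onward 152 of 161 expressed genes (94.4%) had a negative fold change in either treatment, with medians of -0.85 and -0.84, and the 119 genes before 60 Mb had medians of -0.04 and -0.02. The median deviation of the genes from 60 Mb was -0.58 in KI1, -0.84 in KI2 and -0.86 in KI3. It was at lowest -0.04 in the other 11 clones, where the mean was 0.08 ± 0.06 (exact permutation p = 0.00275, two-sided, the smallest of 364 splits). That p-value is no independent support, since the region and its boundary were chosen on these same clones. It also takes the KI clones as independent, which was not tested. Single stretches and genes departed from this division of the clones. In the bin from 130 Mb WT5 stood at -0.757, against -0.521 in KI1, -0.899 in KI2 and -0.798 in KI3. GPC4 and GPC3, in that bin, were the genes from 60 Mb called higher in KI. GPC3 was called after LPS only (212 reads against 1, 172-fold, 95% counting interval 30.6 to 6840), a call lost without KI1, KI2, WT4, WT5 or WT6 (adjusted p up to 0.119), with the KI set fitted alone, with limma voom and without the 4 clones low in proliferation genes. KI1 stood with KI2 and KI3 in the bins from 60 to 80 Mb (-0.865 to -0.942) and less low in those from 100 Mb (-0.415 to -0.601, against -0.788 to -1.043 in KI2 and KI3). Without chromosome X 181 genes remained of the vehicle calls and 288 of the LPS calls. In KO 12 of 429 lower genes lay on it (2.8%).

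**Figure D4:**
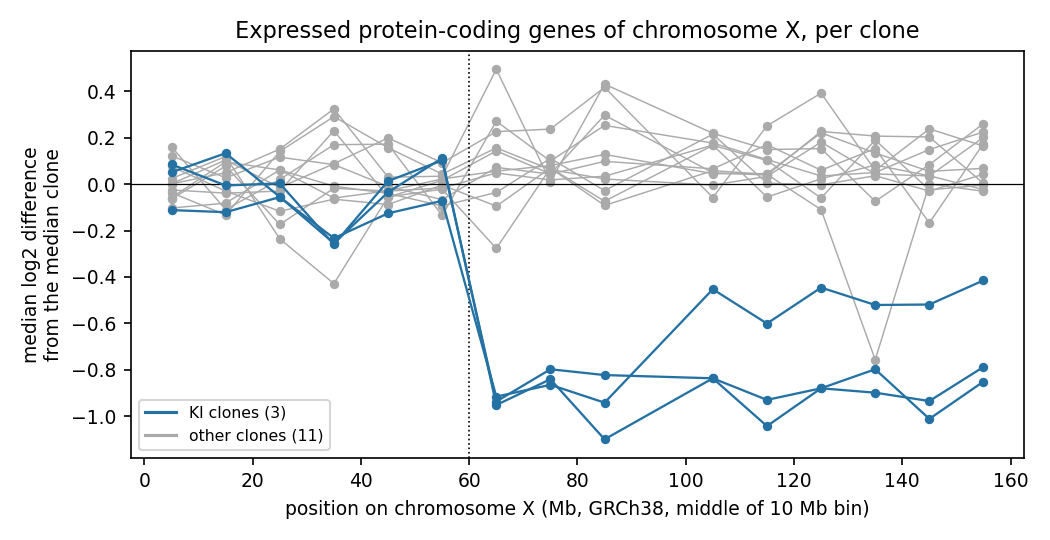
Median log2 difference from the median clone (vertical axis) of expressed genes along chromosome X in bins of 10 Mb (horizontal axis, GRCh38), 1 line per clone, the 3 KI clones in blue and the other 11 in grey. Over the genes from 60 Mb (dotted line) onward the KI clones have medians of -0.58 to -0.86, and the lowest other clone has -0.04.

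The LPS response of the KI clones was not told apart from that of their WT by the unpaired test. TNFAIP3 responded less in KI than in WT by 0.83 in log2, from its higher vehicle level, without passing (adjusted p = 1). NFKB1, TNF and PTGS2 did not pass either. The test of the difference called 0 genes by edgeR (68 at an unadjusted p under 0.05; lowest adjusted p = 1), DESeq2 called 1 and limma voom 0. With the clone as a block 2 genes passed, named here after their values were seen: the carboxypeptidase CPM rose more in KI (log2 difference 2.09, adjusted p = 0.00454) and PSD3 less (-1.72, adjusted p = 0.00514). The NF-kB list had 0 of 32 called (0 adjusted over the list alone, 0 with the block; median 0.11 and mean -0.02), and no list held with an estimated correlation (adjusted p = 0.94). On simulated data for this comparison 4.48% of 2-fold, 64.2% of 4-fold and 69.7% of 8-fold changes were recovered.

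Set against each other, the differences of KO and of KI from their WT were told apart in more genes after LPS than under vehicle. PTGS2, CXCL2 and IRF1 were called higher in KO and not in KI, IL23A was higher in KO and lower in KI, and FADD and SPRY2 were called lower in KO only. For VEGFA, the vascular growth factor, INSIG1, of the sterol pathway, and CHAC1, of the integrated stress response, the KO difference was the higher. FCGR2B, TREM1 and CYBB were lower in KI and not called in KO. The direct test of KO effect minus KI effect called 851 genes after LPS (453 higher, 398 lower; 53.2% higher, 63.9% with RLE size factors and 10.7% with library size alone, which moved the median gene by -0.50). The count was 393 without KI1, 357 without KI2, 379 without KI3, 480 without KO5, 472 without WT1 and 552 without the unsorted WT.

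The difference was 3.30 in log2 for PTGS2 (adjusted p = 0.0042), 8.86 for IL23A (0.00136; 5.74 without WT6), 3.99 for CXCL2 (0.00451), 2.09 for IRF1 (0.00376), -1.08 for FADD (0.00479) and -2.10 for SPRY2 (0.00802). It was 2.94 for VEGFA (0.00572), 2.75 for INSIG1 (0.00561), 3.00 for CHAC1 (0.00588), 4.13 for the protease PLAU (0.0027) and -3.37 for HMOX1 (0.00388). It was 5.06 for FCGR2B (0.0031), 4.11 for TREM1 (0.00521) and 5.50 for CYBB (0.00738). These calls held whichever clone was left out, but IL23A lost its call with limma voom and CYBB without the 4 clones low in proliferation genes. TNFAIP3 differed by 1.85 (adjusted p = 0.0164), a call lost without KI1 (0.0667) and with library size alone. The NF-kB list had 8 of 32 higher (17 adjusted over the list alone; median 1.18) and cytokines 7 of 23 (9 adjusted over the list alone; median 2.41), with adjusted p = 0.115 for each with an estimated correlation. Under vehicle 128 genes differed (105 higher, 23 lower; 82% higher, 56.2% with library size alone, which moved the median gene by -0.17). FCGR2B differed by 5.16 (adjusted p = 0.00658) and PGK1 by 1.75 (0.00538; lost without the 4 clones low in proliferation genes), calls that held whichever clone was left out, and TREM1 by 4.25 (0.0111), lost without KI3 (0.075). That vehicle count was 76 without KI1, 48 without KI2, 37 without KI3, 54 without KO5, 72 without WT1, 73 without the unsorted WT and 291 without WT5.

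Few genes were called in KO and in KI together after LPS. SCAF4 was the only gene higher in both, against 3.74 for independent lists, and ZMYM3, PDE7A and PIK3IP1 were lower in both, against 8.23; these 4 were named after their values were seen. Opposite changes were more frequent, 12 genes higher in KO and lower in KI (8.52 for independent lists), such as IL23A and PLAU, and 15 lower in KO and higher in KI (3.62), such as OXR1 and MAN1A1. Across all tested genes, which are not independent replicates, the fold changes correlated at r = -0.101 after LPS and -0.147 under vehicle. The sets shared no control libraries.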

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

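The tests that weigh an explanation, and the counts over other splits of the samples, were chosen only after the results they weigh were seen. Single libraries stood apart from the other 3 of their group in 12 of 194 groups examined, where chance marks about 1 in 20. Of these, 5 were KO4 after LPS. Its mean for the A20 partner list was 5.57 log2 CPM against 5.33 to 5.36 in the other KO clones, IL20 stood at 3.33 CPM against 1.64 to 1.89, the Fc receptor FCAMR at 91.9 CPM against 4.82 to 19.6, FADD at 21.8 CPM against 14.3 to 14.6 and CHAC1 at 45.0 CPM against 21.4 to 24.5. In WT3 the proliferation list had a mean of 3.30 log2 CPM under vehicle against 5.46 to 5.90 in the other WT clones, and after LPS HMOX1 stood at 119 CPM against 26.1 to 39.7 and IL20 at 0.0845 CPM, from 1 read, against 0. In KO1 after LPS NFKB1 stood at 890.3 CPM against 746 to 766 and BACE2 at 0.455 CPM against 0. CPS1 stood at 12.2 CPM in WT1 after LPS against 6.31 to 6.41, and PIK3IP1 at 38.9 CPM in KO2 under vehicle against 50.4 to 52.1. No biological explanation was tested for these single libraries.

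The LPS response differed between KO and WT in 21 genes, and in 1105 with the clone as a block. The response was larger in KO by a log2 difference of 4.94 for TNF, 2.72 for TNFSF9, 2.18 for TNFAIP3, 1.82 for CITED4 and 1.52 for NFKB1. It was smaller by -1.94 for KBTBD7, -1.53 for PIK3IP1, -1.33 for SLC30A1, -1.29 for RAP2B and -0.95 for FADD. Whichever clone was left out, the 21 fell to between 1 and 14, and among these genes only NFKB1 kept its call without each of the 8 clones. Between KI and WT the response differed in 2 genes with the clone as a block and in 0 without it (68 at an unadjusted p under 0.05 by edgeR; DESeq2 called 1 and limma voom 0).

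The KO effect and the KI effect differed in 128 genes under vehicle and 851 after LPS. Under vehicle the difference was 5.16 in log2 for FCGR2B, 4.25 for TREM1 and 1.75 for PGK1. After LPS it was 1.85 for TNFAIP3, 3.30 for PTGS2, 8.86 for IL23A, 4.74 for IL10, 3.99 for CXCL2, 2.09 for IRF1, -1.08 for FADD and -2.10 for SPRY2. It was 5.06 for FCGR2B, 4.11 for TREM1, 4.13 for PLAU, 2.94 for VEGFA, 2.75 for INSIG1, 3.00 for CHAC1, 5.50 for CYBB and -3.37 for HMOX1. The call of IL10 was lost without KI1, KI3 or WT6 (adjusted p up to 0.0599), that of TNFAIP3 without KI1 (0.0667) and that of TREM1 under vehicle without KI3 (0.075).

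Other splits of the same samples were counted for each contrast. For KO against WT after LPS 1 of the 35 splits, the real one, called as many as its 873 genes, a share under 0.05. A split that mixed KO and WT clones came so close that the count alone does not exclude chance. The highest other split called 857, parting KO1, WT1, WT3 and the unsorted WT from KO2, KO4, KO5 and WT2, so the samples hold a further structure of nearly the same size; it shared 228 genes with the real split, called 22 of 37 interferon-stimulated genes higher in the latter clones and 4 NF-kB members against 17. For KO against WT under vehicle the real count is 0, which 35 of 35 splits reach by construction (highest other 12), so these splits say nothing about chance. For the difference of responses in KO the real split called 21 genes against 1 in the highest other split. With the block it called 1105 against 17 (1 of 35 each, a share under 0.05). This is the smallest share that 35 splits allow, and splits were counted for many contrasts after the results were seen. Chance is thus made less likely for that difference but is not excluded. For the LPS responses 1 of 35 splits, the real one, called as many in the WT of the KO set (1539 against 160) and in KO (4025 against 681). These splits ignore the pairing of libraries by clone. Those that part every pair, 8 in each set, called 0 at most apart from the real one, but are too few for a share under 0.05. The KI set allows too few splits (10) for a share under 0.05: KI against WT under vehicle called 256 genes against 0 in the highest other, KI against WT after LPS 370 against 1 and the difference of responses 0 against 0, which all 10 splits reach by construction. With the block that difference called 2 against 0. Without it the LPS response called 860 genes in KI against 1, and 644 in the WT of the KI set against 1002 (2 of 10), a count above the real one that points to a structure among those libraries; the splits that part every pair, 4 in each, called 0 at most apart from the real one. For the KO effect minus the KI effect 2 of 100 drawn splits called as many under each treatment (128 against 370 under vehicle, 851 against 879 after LPS), a share under 0.05 that rests largely on keeping the KI clones together. With the KI clones kept together, the KO-set clones were assigned in all 70 ways. Under vehicle 5 assignments called as many, so there chance cannot be excluded for the KO part. After LPS 2 did, a share under 0.05, but 1 of them mixed KO and WT clones and called 879, more than the real 851. That count does not exclude chance for the KO part either. The highest other assignment set KO2, KO4, KO5 and WT2 against the rest, as above, and again points to a structure of the samples.

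Genes of chromosome X from 60 Mb onward were low in the 3 KI clones, with GPC4 and, after LPS, GPC3 called higher, KI1 less low from 100 Mb onward, and WT5 as low in the bin from 130 Mb (-0.757). With library size alone the highest KI clone had a median of -0.49 relative to the autosomal genes, a gap that scaling of the libraries cannot make, since it moves all genes of a library alike. Loss of part of chromosome X in the KI clones had the values set for it, though it leaves GPC4, GPC3, the step in KI1 and WT5 unexplained: at least 94.4% of the expressed genes from 60 Mb were lower in each treatment, and those before 60 Mb had medians near 0. An effect of the C103A change on these genes cannot be told apart from such a loss, because every clone with the change was low (highest median -0.58) and none had the change alone. A candidate explanation is therefore a chromosomal change carried by these clones, a hypothesis found and tested on the same counts, with no DNA examined.

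NF-kB target and cytokine genes were higher in the KO clones after LPS. With library size alone 14 of 32 NF-kB members were still called higher, which argues against scaling of the libraries; the gap of 1.32 between the median of that list and of all genes tests nothing, since scaling moves all genes of a library alike. With the interferon list as a covariate 19 NF-kB members and 11 of 23 cytokines were called higher. With the proliferation list 18 and 11 were. Such counts can rise with any covariate, as the chromosome 6 segment gave 21 and 13, so they do not weigh a cause. The list medians were 1.28 and 2.60 without a covariate, 1.11 and 2.29 with the interferon list and 1.25 and 2.52 with the proliferation list. They argue against the interferon state, or fewer dividing cells in some clones, as the whole of the difference. Leaving out the 4 clones low in proliferation genes left 12 and 5 calls, with fewer samples, and medians of 1.00 and 2.34. What stays open is any other difference between the clones, which the split that called 857 genes shows to be large. Loss of the A20 brake may raise these genes, as a hypothesis from the same data.

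Interferon-stimulated genes differed between clones of the same genotype, most of all in the KO set. The list means, in log2 CPM, were averaged over the vehicle and LPS library of each clone. They were 2.41 in KO1, 5.41 in KO2, 6.14 in KO4 and 4.82 in KO5. In the WT they were 2.98 in WT1, 6.23 in WT2, 2.93 in WT3 and 4.62 in the unsorted WT. Knock-out of A20 as what sets the level is argued against, since the lowest KO clone lay at -0.52 relative to the lowest WT clone, and so is scaling, since with library size alone the 8 clones still spanned 3.86. That the C103A change sets the level could be neither excluded nor shown: the 3 KI clones were at 2.68 to 3.28 and 2 of the 7 WT clones lay at or below the highest of them. Under vehicle alone the list mean ran from 2.59 in KO1 to 5.74 in KO4, and from 2.57 in WT1 to 5.73 in WT2. The spread between clones was thus present without LPS. A state of each clone that predates PMA is a possible explanation that was not tested.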

How the results depend on the processing

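The tests with library size alone, with a covariate, without the 4 clones low in proliferation genes and without chromosome X were chosen only after the results were seen; the other alternatives were chosen at the outset. With RLE size factors no count of called genes moved by more than 1.5 times, TNFAIP3 after LPS in KO was 2.14 against 2.10, 113 list tests passed against 115, and 4 genes were called in KO and KI alike, as with TMM. In every case below the cause was not tested, except that leaving out clones or libraries leaves fewer samples. Depth limits genes of few reads: with 0 reads taken as at most 3, the shallowest library (7539406 counts) could miss a gene below 0.398 CPM, and folds of such genes are bounds.

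DESeq2 called 9 genes for KO against WT under vehicle, 538 for KI against WT under vehicle, 795 for KI against WT after LPS, 121 for the difference of responses in KO, 1 in KI, 372 for KO effect minus KI effect under vehicle and 1350 after LPS. Without a filter on low counts the calls were 486 for KO against WT after LPS, 241 for KI against WT after LPS, 5 for the difference of responses in KO and 495 for KO effect minus KI effect after LPS. With limma voom and the clone as a random effect they were 1 for KO against WT under vehicle, 511 for KO against WT after LPS, 5283 for the LPS response in the WT of the KO set, 7517 in KO, 3680 in the WT of the KI set, 4378 in KI and 1208 for the difference of responses in KO. With only the libraries of the set in the fit that difference called 8.

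With the replicate block, where the clone pairs the libraries, the LPS responses called 5513 in the WT of the KO set, 7765 in KO, 3845 in the WT of the KI set and 4369 in KI, and the differences of responses 1105 in KO and 2 in KI. Among the named genes of these responses and differences it changed no other call. Between KO and WT the clone numbers 1 and 2 were taken as shared labels only, which is an assumption. Same-numbered clones correlated at r = 0.31 and -0.069. As a replicate block the numbers gave 17 genes under vehicle and 838 after LPS. Among the named KO calls after LPS that block ended those of IL20, IL1A, CSF2 and others, and kept those of TNF, PTGS2, CXCL2 and others.

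With library size only the calls were 3175 for KO against WT after LPS, 2949 for the LPS response in the WT of the KO set, 7329 in KO, 1049 in the WT of the KI set, 57 for the difference of responses in KO and 2614 for KO effect minus KI effect after LPS. That scaling reversed the LPS response in KO of MT-CO1 (-0.04) and MT-CO2 (-0.064), which were 0.58 and 0.55 with TMM. With the chromosome 6 segment as a covariate the calls were 7 for KO against WT under vehicle, 1317 after LPS, 623 for KI against WT under vehicle, 841 after LPS, 45 for the difference of responses in KO, 595 for KO effect minus KI effect under vehicle and 2011 after LPS. With the proliferation list as a covariate they were 418 for KI against WT under vehicle, 607 after LPS, 992 for the LPS response in the WT of the KI set and 55 for the difference of responses in KO, which the interferon list as a covariate put at 40. Without the 4 clones low in proliferation genes they were 1 and 487 for KO against WT under vehicle and after LPS, 470 and 736 for KI against WT, 2542 for the LPS response in KO, 1579 in KI, 1 for the difference of responses in KO, and 83 and 517 for KO effect minus KI effect. Without chromosome X the counts were 181 and 288 for KI against WT and 95 and 784 for KO effect minus KI effect, under vehicle and after LPS.

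Leaving out each clone in turn gave 0 to 3 calls for KO against WT under vehicle, 298 to 1116 after LPS, 65 to 424 for KI against WT under vehicle and 69 to 477 after LPS. For LPS responses it gave 757 to 1115 in the WT of the KO set, 2963 to 3189 in KO, 196 to 394 in the WT of the KI set and 203 to 383 in KI. It gave 1 to 14 for the difference of responses in KO and 0 in KI, and 37 to 291 and 357 to 1144 for KO effect minus KI effect under vehicle and after LPS.

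TNFAIP3 under vehicle in KO, -0.08 without a call, ran from -0.346 without WT3 to 0.213 without WT2, and changed sign to 0.112 with limma voom, to 0.071 with the proliferation list as a covariate and to 0.031 without the unsorted WT. In KI under vehicle TNFAIP3 passed with DESeq2 (adjusted p = 0.0424) and without the 4 clones low in proliferation genes (0.0486), with adjusted p otherwise above 0.05. Of the 240 list tests 16 passed with an estimated inter-gene correlation and 51 with fry. Requiring an absolute log2 fold change of at least 1 left 1 gene called in KO and KI alike. For the 316 values of single named genes, 3106 values under other settings and 1487 with a clone left out kept direction and side of the threshold, 293 and 563 kept direction and lost the call, and 2 gained it.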

Other observations

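The tests of whole profiles between clones, of the WT clones of both sets against each other, of the chromosome 6 segment and of whole chromosomes were chosen only after the results were seen. The 3 KI clones resembled each other more than any other clones did. For each clone the deviation of every expressed protein-coding gene from the median of the 14 clones under the same treatment was averaged over both treatments. Across genes, which are not independent replicates, these profiles correlated at 0.74 or more between KI clones, at 0.35 at most between a KI clone and another, and at 0.55 at most between clones outside KI. The WT clones of the KO set and of the KI set differed in 0 genes under each treatment, with 448 and 998 at an unadjusted p under 0.05 (edgeR quasi-likelihood). No explanation of the resemblance was tested. If the KI clones share a recent parent cell, the KI p-values do not rest on 3 independent clones.

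Besides the genes named in the report, the transcription factor BACH1 was higher in KO (1.04) and lower in KI (-1.07) after LPS, as were the adaptor GAB2 (0.84 and -0.81), NECTIN2 (1.16 and -1.53) and the small GTPases RAB12 (1.496 and -1.04) and RAP2A (1.09 and -1.42). KLF10 (-1.44 and 1.65) and the matrix gene MFAP4 (-3.58 and 2.73) went the other way. These genes were named after their values were seen. The KO and KI fold changes came from clones and control libraries that were not shared.

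Genes of chromosome 6 between 40 and 60 Mb split the clones: their mean log2 CPM was 5.01 to 5.06 in the 3 KI clones, 5.06 in WT6, 5.10 in KO4 and 5.09 in WT2, against 5.70 to 6.08 in the others. Single clones also had shifts of other whole chromosomes. The median gene of chromosome 20 stood at -0.56 in WT5, that of chromosome 13 at -0.34 in KI3 and that of chromosome 19 at -0.34 in WT6.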
